A study of Oryza sativa with 2 samples.

How the data were processed

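RNA was measured in 2 samples of rice endosperm, hand-picked 2 days after pollination from plants grown with 12 h of light at 28 °C and 12 h of dark at 22 °C. Per the labels' protocols, total RNA was extracted with an RNeasy Mini Kit, amplified and biotin-labelled with the GeneChip 3' IVT Express Kit and hybridized to Affymetrix rice arrays. The deposited values are linear signal intensities, 1 per probe set and array, and MAS5 is named in the submitters' processing notes; its version and settings are not given in the sources used here, and detection calls were not used here. The mean of each array without its lowest and highest 2% of values was 500.1 on both, so the arrays had been scaled one by one. The median signal was 42.1 on array 1 and 33.4 on array 2. The number of arrays limits the precision of every value.

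Values were used as deposited, on the log2 scale. Of 57381 probe sets, 187 were controls, which left 57194 for rice. Background on each array was the 95th percentile of its 64 probe sets against reporter or transgene sequences. All 10 probe sets against the rice blast fungus were at or below it on both arrays. The 3' to 5' signal ratio of the rice control genes was 13.1 and 13.7 for actin, 3.55 and 4.45 for GAPDH, and 3.51 and 2.99 for cyclophilin on arrays 1 and 2. For added bacterial control transcripts it was high as well, at 9.44 and 9.43 for dap, and 7.88 and 14.0 for thr. The rice ratios alone therefore do not measure the state of the endosperm RNA.

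Genes came from the platform's probe annotation of 2016. It listed 22436 probe sets with 1 gene, 95 with several and none for 34850, of which 34663 were rice probe sets and the rest controls. These rice probe sets are called unnamed here, and whether they have a gene is not known from this annotation. All 17905 genes with a single-gene probe set were found in the gene table of assembly ASM3414082v1, which was used for names only, and 2457 of them had a symbol or synonym. Each gene was read through 1 probe set, by suffix (_at, then _a_at, _s_at and _x_at) and then by the highest mean. Of 477 list genes, 99 had several probe sets, 62 of these over 4-fold apart, and 10 genes not above background on both arrays in the chosen probe set were so in another.

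Gene lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined. Of 83 members fixed by identifier, 49 names matched a usable gene through symbol, synonym and chromosome, for 48 genes; 29 had no match, 2 had no single-gene probe set, 2 lay over 6 Mb from the expected position and 1 matched several genes. The gene tables hold no protein descriptions, so lists planned by description were matched by symbol patterns. These patterns, and 10 further lists, were written after the tables were seen but before any gene's signal was read: MADS-box factors, meiosis, auxin, cytokinin, late seed maturation, small RNA pathway, cellulose synthases, expansins, aquaporins and calcium sensors. No phragmoplast or callose gene was found, so that list holds kinesins alone. The named genes are all list members fixed by identifier, the 3 with the highest mean signal of each list matched by symbol, the 20 brightest named genes and the 5 with the widest difference in each direction.

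With 1 group there was no test between groups. For each of 25 lists of at least 4 genes, the median of the mean log2 signals was set against 10000 random gene lists of the same size, and the median difference, array 2 minus array 1, against 10000 random lists matched on signal in 20 bins. Lists outside the middle 95% of random lists were counted as standing apart. Genes among the brightest 5% on both arrays, 845 in all, were counted per list with a 2-sided Fisher's exact test and Benjamini-Hochberg adjustment over the lists. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and, for plots, matplotlib 3.10.9.

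The steps were tested on simulated data with the real arrays' mean signals and spread by signal, 57381 probe sets and 17905 genes. Both simulated arrays had the same means and independent noise. The real difference between the arrays by signal, and any shared variation within a gene family, were thus absent. Of 40 random lists of 20 genes, 3 lay outside the level percentiles and 1 outside the shift percentiles. Of 5 lists drawn from bright genes, 5 lay above the level percentiles and 4 passed the adjusted Fisher's exact test, which no unchanged list did. All 5 lists shifted by 0.50 lay above the shift percentiles. Of 50 genes raised 3-fold on 1 array, 50 were counted as differing over 2-fold, against 25 of 50 raised 2-fold. The raised genes and the shifted lists were drawn from bright genes only, so recovery among dim genes was not tested. Neither were shifts in shorter lists or shifts smaller than 0.50. The bright lists were drawn from the brightest genes, so their place above the level percentiles was fixed in advance. These counts show that the steps ran as meant, and not how often the real list calls are wrong.

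The alternatives were other backgrounds, quantile normalization, subtracting each array's median, other rules for several probe sets, an added offset of 16, other filters on dim probe sets, the brightest 10%, and each array alone. Random lists from genes with a symbol were added after the data were seen, since list members were found by symbol.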

Results

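The series profiled endosperm of the japonica rice cultivar Zhonghua11 at 2 days after pollination, a stage that the labels place before cellularization, when the tissue still divides as nuclei in a shared cytoplasm. Endosperm is the seed tissue that later stores starch and protein. There was 1 group of 2 samples, each hybridized to 1 Affymetrix rice array, and the stated aim was the expression profile of this stage. No second tissue or stage was measured here, so the values below are levels and the spread between the arrays, with no group effect. The labels do not say that the 2 samples came from separate plants, so the spread may be technical, and with 2 arrays it is itself poorly known.

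Transcripts were detected from a large part of the rice probe sets. Of 57194 rice probe sets, 24467 (42.8%) were above background on both arrays, 1631 on array 1 only and 2858 on array 2 only. Below, a gene is called above background only if its signal was so on both arrays. Of 17905 genes read through a probe set listed for 1 gene, 13263 (74.1%) were above background on both arrays. Background was a signal of 52.7 on array 1 and 37.9 on array 2, from probe sets against reporter sequences that untransformed rice should lack. The median log2 signal over the genes was 8.58, and that of 10000 random lists lay close to it for every list size.

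Most of the starch and sucrose genes read were bright in these samples. Some markers of other tissues, given below, were above background too. All 5 starch synthesis genes read were above background, with a median log2 signal of 13.00, at the 99.95th percentile of random lists of 5 genes. They were the small subunit AGPS2 of ADP-glucose pyrophosphorylase, which makes the sugar donor (14.18 ± 0.10, log2, SD, n = 2), the soluble starch synthases SSI (13.00 ± 0.24) and SSIIa (13.46 ± 0.23), the amylose-making granule-bound synthase GBSSI (12.73 ± 0.18) and the branching enzyme BEI (6.66 ± 0.17). Probe sets of BEI and GBSSI disagreed: the brightest of 8 for BEI stood at 12.93 and the brightest of 6 for GBSSI at 14.18, while the dimmest of each were below background. With the mean over all probe sets of each gene, the starch list lay at the 82.2nd percentile, inside the range of random lists. Of the 5 genes, 2 were among the brightest 5%, which did not pass the test (adjusted p = 0.0843, 2-sided Fisher's exact test over 25 lists). That test passed with the brightest probe set of each gene (adjusted p = 0.00486, 3 of 5 genes) and with the brightest 10% (0.00190, 4 of 5), both Fisher's exact tests. It passed on array 1 alone (adjusted p = 0.00579, 3 of 5) but not on array 2 alone (0.0942, 2 of 5), again by Fisher's exact test. The other starch genes of the plan, among them BEIIb, SSIIIa and PUL, found no usable match and were not analysed here.

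Of 9 sucrose supply genes, 8 were above background, and the list's median of 12.77 lay at the 99.97th percentile. The sucrose synthases SUS1 (12.84 ± 0.22), SUS2 (13.14 ± 0.12), SUS3 (14.64 ± 0.01) and SUS4 (11.35 ± 0.02), which split sucrose, were all above background. So were the sugar transporters SWEET11 (13.57 ± 0.16) and SWEET4 (11.51 ± 0.05), the sucrose transporter SUT1 (12.77 ± 0.08) and the cell wall invertase GIF1 (7.86 ± 0.19). SWEET14 was above background on array 2 alone in the probe set read (5.31 ± 0.24) and on both arrays in its other probe set. SUS2, SUS3 and SWEET11 were among the brightest 5% of genes on both arrays, more than chance gives (adjusted p = 0.0355, 2-sided Fisher's exact test over 25 lists). Against genes with a symbol alone, a comparison added after the data were seen, that call was lost (adjusted p = 0.111, Fisher's exact test). It was also lost with the brightest probe set of each gene, a rule fixed before the data were examined, where 2 of 9 genes were that bright (adjusted p = 0.229, Fisher's exact test).

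The storage protein and alpha-amylase lists had low medians. Of 7 seed storage protein genes, 2 were above background, the glutelin genes GluA2 (7.84 ± 0.29) and GluB5 (6.69 ± 0.63), and the list's median of 4.62 lay at the 1.95th percentile. GluA1 (2.91 ± 4.43), GluA3 (3.90 ± 0.99), GluB4 (4.62 ± 0.24), GluD1 (0.35 ± 0.15) and the prolamin gene PROLM25 (4.71 ± 3.30) were not above background on both arrays. On array 2 alone the storage list lay at the 11th percentile, so its low place rests on array 1. PROLM25 was the only prolamin gene in the list. GluB1 of the plan had no match, and GluC and Glb1 were left out because their matches lay far from the expected position. None of 5 alpha-amylase genes, RAmy1A, RAmy3D, RAmy3A, RAmy3E and AMYC2, was above background, and this list's median of 2.61 lay at the 0.26th percentile.

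Most genes of DNA replication and the cell cycle were above background. Of 23 replication genes, 22 were above background, and the median of 11.32 lay at the 99.97th percentile. All 6 subunits of the MCM2 to MCM7 helicase were detected: MCM2 at 12.64 ± 0.07, MCM3 at 12.02 ± 0.06, MCM4 at 12.00 ± 0.05, MCM5 at 11.89 ± 0.02, MCM6 at 10.79 ± 0.02 and MCM7 at 11.32 ± 0.15. PCNA, the sliding clamp of DNA polymerase, stood at 13.05 ± 0.16 and RPA3, a subunit of the single-strand binding complex, at 13.01 ± 0.02, with RPA2A at 11.98 ± 0.04 and RPA1B at 11.97 ± 0.05. MCM8 was below background. Of 19 cyclins and cyclin-dependent kinases, 17 were above background, with CYCB2-2 at 13.20 ± 0.08, CYCB1-1 at 13.12 ± 0.16, CYCB2-1 at 12.19 ± 0.02 and the mitotic kinase CDKB2 at 12.71 ± 0.00. CYCD5-2 stood at 12.67 ± 0.15 and CYCA2-1 at 12.02 ± 0.02. CYCD5-1 and CYCD3-2 were not above background on both arrays. CDKA2 stood at 9.39 ± 0.02. CDKA1 read 6.42 ± 0.09 in its chosen probe set and 11.87 in the other. The median of this list, 10.27, lay at the 95.8th percentile, inside the range of random lists.

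Histone H2B, tubulin and actin, ribosomal protein and proteasome genes were among the brightest 5% more often than other genes. The histone list held 5 H2B genes, all on chromosome 1, and CenH3, with no H2A or H4 gene and no other H3 gene. Of these 6 genes, the 5 H2B genes were among the brightest 5% (adjusted exact p = 8.34e-06), with H2B.5 at 14.20 ± 0.13, H2B.6 at 13.96 ± 0.11 and H2B.11 at 13.89 ± 0.09. Of 15 tubulin and actin genes, 10 were (adjusted exact p = 1.05e-09), with TUBB5 at 14.57 ± 0.12, the alpha-tubulin gene TID1 at 14.41 ± 0.00 and ACT1 at 14.37 ± 0.35. Of 22 ribosomal protein genes, 18 were (adjusted exact p = 1.73e-19), with RPS21 at 14.84 ± 0.01, RPL39B at 14.73 ± 0.09 and RPL9 at 14.68 ± 0.09. Of 15 proteasome genes, 11 were (adjusted exact p = 3.48e-11), with PAE1 at 13.91 ± 0.17, PBD1 at 13.82 ± 0.03 and PBC1 at 13.54 ± 0.05. Fisher's exact test treats genes as independent units, so these p-values describe the 2 arrays and not a population of plants. Related genes such as the H2B genes may share signal between probe sets, which would make their p-value too small. Of 32 kinesin genes, the motors that move along microtubules, 29 were above background, with KIN14N at 12.42 ± 0.03, KIN10A at 12.36 ± 0.08 and KIN13A at 12.30 ± 0.03. Their median of 10.38 lay at the 99.2nd percentile, and at the 96.3rd among genes with a symbol, which is inside the range of random lists.

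Chromatin regulators were detected. The maintenance DNA methyltransferase genes MET1b and MET1a stood at 13.30 ± 0.03 and 8.75 ± 0.17, the chromomethylase CMT3a at 11.51 ± 0.07 and the de novo enzyme DRM2 at 11.14 ± 0.05, and the median of these 4 genes lay at the 95.8th percentile. A Polycomb gene listed as fie, which is not told apart here between FIE1 and FIE2, stood at 12.98 ± 0.09, and the histone methyltransferase gene EZ1 at 9.48 ± 0.00. Of the endosperm regulators, NF-YB1 stood at 11.46 ± 0.20, RSR1 at 7.07 ± 0.36 and MADS6 at 5.97 ± 0.20. MADS6 was close to background, with signals of 69.1 and 56.9 against 52.7 and 37.9 on arrays 1 and 2. Most of the planned regulators, among them RPBF, RISBZ1 and FLO2, found no match and were not analysed here. Nor were the Polycomb genes EMF2a, EMF2b and CLF or the methylation list's DDM1 and ROS1a. The elongation factor gene EF-1-alpha and GAPC2, used as reference genes, stood at 14.78 ± 0.01 and 7.43 ± 0.26. GAPC2 was read through its 1 probe set, at signals of 195.0 and 151.8 on arrays 1 and 2. The arrays' 3' control probe set for GAPDH read 15287.9 and 17529.9, so the GAPC2 value does not stand for GAPDH as a whole.

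Some markers of other tissues were above background. Of 4 seed coat, nucellus and embryo markers, MADS29 (8.33 ± 0.11) and MADS21 (7.02 ± 0.21) were above background, while MADS13 (5.45 ± 0.11) and the meristem gene OSH1 (1.88 ± 2.35) were not. Of 9 photosynthesis genes, 6 were above background. The chlorophyll-binding protein gene CAB2R stood at 11.49 ± 0.09, RCABP89 at 7.74 ± 0.20 and the oxygen-evolving complex gene OEE3 at 7.52 ± 0.07. The medians of these lists lay at the 15.7th and 17.4th percentiles, inside the range of random lists. Whether other tissue, picked along with the endosperm, added to the levels of any list was not tested. No level given here is therefore tied to endosperm alone. Of 23 heat shock protein genes, 15 were above background, with HSP81-2 at 14.58 ± 0.23, HSP81-1 at 14.16 ± 0.04 and HSP26.2 at 12.04 ± 0.23, and the median lay at the 32.4th percentile.

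**Figure D1:**
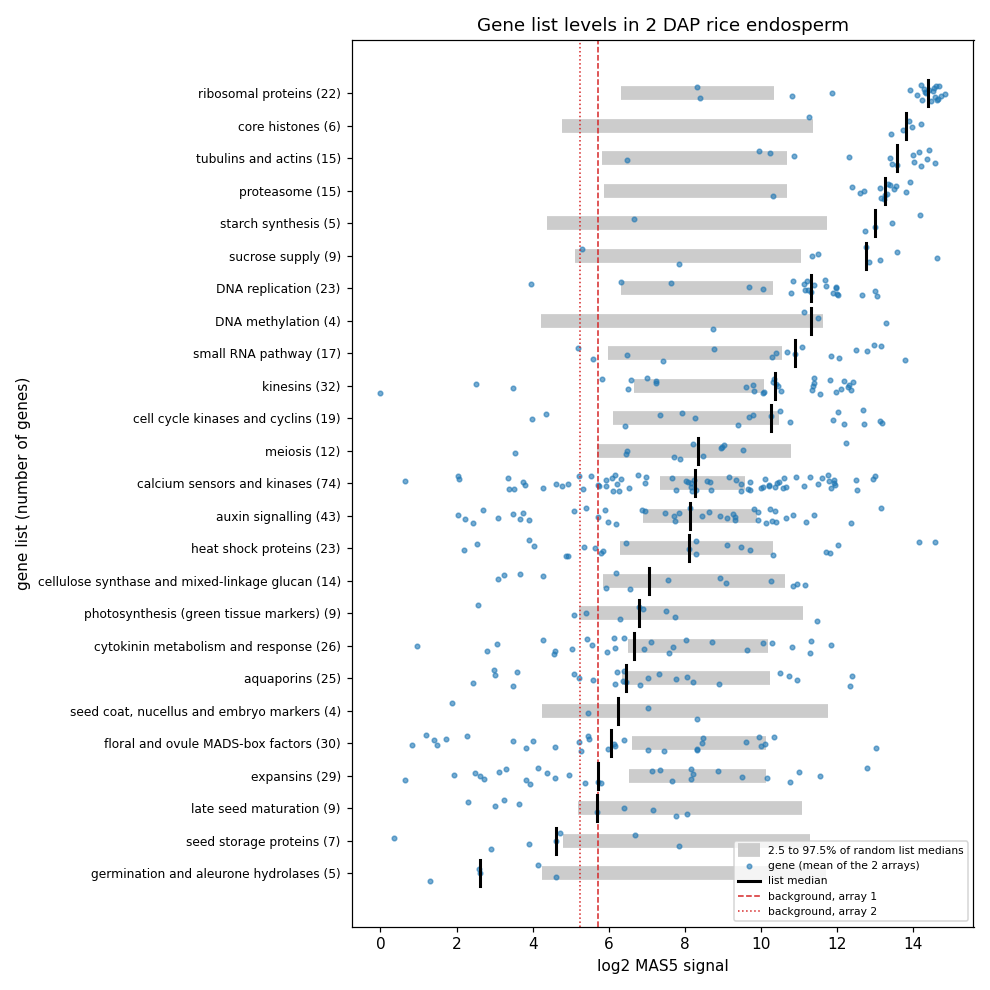
Each dot is a gene's mean log2 MAS5 signal over the 2 arrays (x axis), grouped by gene list (y axis, with the number of genes), black bars are list medians, grey bars hold the middle 95% of random list medians and red lines mark each array's background. The medians of ribosomal protein, histone, tubulin and actin, and proteasome genes lie between 13.27 and 14.38, right of the random range, and that of the alpha-amylase list lies at 2.61, left of it.

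The 20 brightest named genes on both arrays, listed as bright probe sets and not as an order of transcripts since probe affinity differs, included 9 ribosomal protein genes. Besides RPS21, RPL39B and RPL9 these were RPL5, RPS27AA, RPL7A-2, RPS4, RPL7A-1 and RPL11. The others were EF-1-alpha, SUS3, HSP81-2, TUBB5, the calreticulin gene CRO1, the protein disulfide isomerase gene PDIL1-1, the adenine nucleotide translocator ANT, the ubiquitin fusion gene UBQ2, the scaffold gene RACK1A, the GTPase gene RAN2 and PP37. Their mean log2 signals ran from 14.50 for RAN2 to 14.84 for RPS21.

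The 2 arrays differed little where signal was high. Across 57194 rice probe sets the log2 signals correlated with Pearson's r of 0.936 and Spearman's rho of 0.913, over probe sets, which are not replicates. The SD between the arrays was 0.89 over all probe sets, 0.24 over those above background on both arrays, 0.12 in the brightest 10% and 1.49 in the dim group with the widest spread. Dim probe sets were dimmer on array 2, by a median log2 difference of -0.51 in the dimmest 10% against 0.02 in the brightest.

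**Figure D2:**
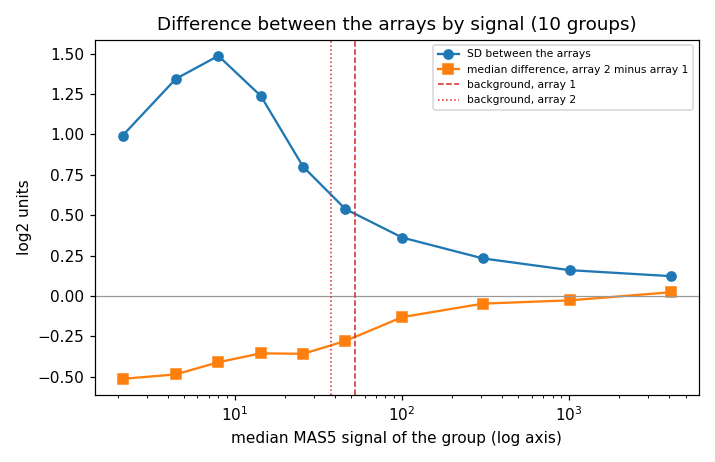
The SD between the arrays (circles) and the median log2 difference, array 2 minus array 1 (squares), are plotted in log2 units against the median MAS5 signal of 10 groups of rice probe sets, cut by signal, on a log axis, with red lines at each array's background. The SD peaks at 1.49 in a group left of both backgrounds and reaches 0.12 in the brightest group.

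Of the 24467 probe sets above background on both arrays, 420 (1.72%) differed by over 2-fold, 100 higher on array 2 and 320 higher on array 1. Among named genes the widest gaps with array 2 higher were those of the calmodulin-like gene CML16 (log2 difference 2.01), SAP17 (1.40), XBOS35 (1.26), the calcium sensor CBL2 (1.25) and UGE-1 (1.08). With array 1 higher they were those of cdsp32 (-1.36), the metallothionein gene MT-2 (-1.30), the metal transporter NRAMP4 (-1.26), the meiosis gene PAIR1 (-1.13) and the silicon transporter Lsi1 (-1.08). These last 5 were dim on array 2, with signals from 39.3 to 62.1 against a background of 37.9. The 5 genes higher on array 2 had signals of at least 104.7 on array 1, where background was 52.7. With the highest reporter probe set as background, 90 probe sets differed, 63 of them higher on array 2, so the split by direction rests on dim probe sets.

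All 5 starch synthesis genes were dimmer on array 2, by a median log2 difference of -0.25, at the 0.13th percentile of random lists matched on signal. The differences were -0.25 for GBSSI, -0.33 for SSI, -0.33 for SSIIa, -0.24 for BEI and -0.14 for AGPS2. The storage protein list (0.89, 98.9th percentile) and the cytokinin list (0.14, 98.8th percentile) lay at the other end. Of the 7 storage genes, GluA1 and PROLM25 were above background on array 2 alone, and GluA3, GluB4 and GluD1 on neither array. With only genes above background on both arrays the cytokinin list lay inside the random range (0.04, 84.4th percentile), as it did with an offset of 16 (94.98th percentile). Chance puts 1.25 of 25 lists outside the middle 95% of random lists, and 3 were. Sucrose supply (-0.01), replication (0.01), cell cycle (0.00), kinesin (0.00), tubulin and actin (0.00), methylation (-0.08), proteasome (0.07), ribosomal protein (0.09), heat shock (0.10) and histone genes (0.17) lay inside that range. So did the seed coat (0.00), photosynthesis (-0.23) and alpha-amylase lists (-1.14), and the further lists other than cytokinin. Heat shock genes lay outside it after quantile normalization (99.4th percentile) and with only genes above background (99.7th), auxin genes after quantile normalization (0.13th) and with the offset (1.69th), small RNA genes with probe sets averaged (0.13th) and histone genes against genes with a symbol (98.1st).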

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

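All tests of causes in this part were chosen after the pattern was seen.

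Outside the gene lists, 8488 of 34663 rice probe sets with no gene listed here (24.5%) were above background on both arrays, a signal in data that the gene comparisons did not use. Their median log2 signal was 7.54 and their SD between the arrays 0.29. Of the brightest 5% of rice probe sets, 2860 in number, 392 were of this kind. Among the 22531 probe sets with a gene listed, 15979 (70.9%) were above background.

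The 5 starch synthesis genes were dimmer on array 2 together, by a median of -0.25. An intensity-dependent difference between the arrays is argued against by the matching on signal itself, where the list lay at the 0.13th percentile. Quantile normalization left it at the 0.09th percentile, which adds little, since those lists were matched on signal too. For GBSSI and BEI a fault of the probe set read is argued against, but only weakly. Of their 8 other probe sets above background, 7 were dimmer on array 2, with a median difference of -0.25. All rice probe sets above background on both arrays had a median difference of -0.04. The 8 read the same genes repeatedly and are not independent. For SSI, SSIIa and AGPS2 such a fault stays open, with 0 other probe sets above background to judge by. Less maternal tissue on array 2 stays open: the 8 marker genes above background had a median difference of -0.0509 with an SD of 0.30, 4 of them lower. No biological explanation was tested, since the design has 1 group.

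Probe sets for bacterial transcripts, which are control RNAs, were brighter on array 2 by a median log2 difference of 0.25, in 53 of 61 probe sets above background. An intensity-dependent difference is argued against, since rice probe sets had a median difference of only 0.02 in the brightest 10% and lower ones in all dimmer groups. The control median lay at the 100.0th percentile of rice probe sets matched on signal. That percentile is too extreme, because the 61 probe sets read a few transcripts, each several times, and are not independent. Less labelled RNA at hybridization as the whole cause would leave transcripts normally added before labelling (dap, lys, phe and thr) no brighter. They were brighter by a median of 0.26 with an SD of 0.23, higher in 28 of 34 probe sets. This argues against that cause only weakly, since the SD is over probe sets and not over transcripts. Whether less rice RNA entered the labelling was not tested.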

How the results depend on the processing

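No paired analysis was possible because there was 1 group. The count above background stayed within 1.5-fold under all 5 alternatives. Subtracting medians left every list result and gene level as it was, both backgrounds every list level and quantile normalization every Fisher test, so these are not counted. Of the rest, 142 of 150 level values, 139 of 147 differences and 144 of 150 Fisher tests kept their side of the threshold, and none reversed. Of 48 genes, only the 12 with several probe sets can move with the probe set rule, and of these the levels of 10 moved by over 1 SD with averaged and 6 with brightest probe sets. None of the 48 moved so far with quantile normalization. With 2 arrays, leaving 1 out cannot move a level by 1 SD, so that says nothing of stability.

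With the highest reporter as background 90 probe sets differed over 2-fold, with an offset of 16, 219 (72 higher on array 2), and with no filter 16705 (5794 higher on array 2). The SD between the arrays was 0.37 with the offset (r 0.98) and 0.24 above background (r 0.989, rho 0.986). Quantile normalization moved heat shock (99.4) and auxin (0.13) differences outside the random range; the offset moved auxin (1.69) outside and cytokinin (94.98) inside; keeping genes above background moved heat shock (99.7) outside and cytokinin (84.4) inside, and left 3 lists too small for a value. Averaged probe sets put starch levels at 82.2 (inside), cytokinin levels at 1.42 and small RNA differences at 0.13 (outside). Brightest probe sets put cytokinin levels at 1.91 and gave adjusted p of 0.00486 for starch (0.0843 in the planned test) and 0.229 for sucrose supply. The brightest 10% gave 0.00190 for starch. Against genes with a symbol, added after the data were seen, kinesin (96.3) and small RNA (96.3) levels were inside, cytokinin (2.25) and aquaporin (1.79) levels and histone differences (98.1) outside, with adjusted p of 0.111 for sucrose supply and 0.0295 for calcium genes, 0 of 74 among the brightest. The cause was not tested. With 1 array left out, storage levels ran from 0.25 to 11 and starch adjusted p from 0.00579 to 0.0942. Agreement and differences need both arrays. Signal over background limits dim genes.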

Other observations

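Small RNA pathway genes were bright in these samples: 15 of 17 were above background, with a median log2 signal of 10.89 at the 99.1st percentile of random lists. AGO4A, an Argonaute of RNA-directed DNA methylation, stood at 13.80 ± 0.01 (SD, n = 2), AGO18 at 13.17 ± 0.13 and SGS3, a partner in making double-stranded RNA, at 12.96 ± 0.27. Among genes with a symbol the list lay at the 96.3rd percentile, inside the range of random lists. Of 12 meiosis genes, 11 were above background, with OsSPO11-4 at 12.23 ± 0.02, CRC1 at 9.52 ± 0.02 and ASY1 at 9.02 ± 0.10, and the median of 8.35 lay at the 44.3rd percentile.

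The MADS-box and expansin lists had low medians. The MADS-box list was matched by symbol alone, whatever the role of the gene, so it does not describe floral genes as a group. Of 30 MADS-box genes, 16 were above background and the median of 6.05 lay at the 0.55th percentile, yet MADS22 stood at 13.02 ± 0.02, MADS24 at 10.33 ± 0.01 and MADS58 at 10.11 ± 0.19. Of 29 expansin genes, which loosen cell walls, 13 were above background and the median of 5.73 lay at the 0.24th percentile, with EXPB4 at 12.79 ± 0.17, EXPA10 at 11.54 ± 0.08 and EXLA3 at signals of 2031 and 2062 on arrays 1 and 2. Of 14 cellulose synthase and mixed-linkage glucan genes, 10 were above background. CESA1 stood at 11.15 ± 0.11, CESA8 at 10.96 ± 0.07 and CESA5 at 10.85 ± 0.37, and the list lay at the 14.4th percentile.

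Levels of hormone and transport lists lay inside the range of random lists, but cytokinin and aquaporin genes did so only in part of the settings. Auxin signalling genes had 31 of 43 above background (28.6th percentile), led by ARF24 (13.16 ± 0.09), ARF1 (12.38 ± 0.09) and IAA17 (11.38 ± 0.04). Cytokinin genes had 16 of 26 (3.50th percentile), with RR42 at 11.84 ± 0.01, RR33 at 11.30 ± 0.02 and LOGL1 at 11.29 ± 0.22. The cytokinin list lay below that range with averaged probe sets (1.42), brightest probe sets (1.91) and against genes with a symbol (2.25). Aquaporin genes had 16 of 25 (3.0th percentile), with PIP1-2 at 12.39 ± 0.05, SIP1-1 at 12.33 ± 0.05 and TIP1-1 at 10.96 ± 0.01; against genes with a symbol the list lay below the range (1.79). PIP2-1 read 3.59 in its chosen probe set and 13.04 in its brightest. Calcium sensor and kinase genes had 57 of 74 (29.3th percentile), with CBL6 at 12.99 ± 0.01, CML7 at 12.94 ± 0.02 and CPK1 at 12.53 ± 0.02. None of the 74 was among the brightest 5% (adjusted p = 0.181, and 0.0295 against genes with a symbol, Fisher's exact test). Late seed maturation genes had 4 of 9 (4.79th percentile), with TIP3-2 at 8.07 ± 0.08, VP1 at 7.77 ± 0.31 and LEA19 at 7.18 ± 0.19.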
